A study of Mus musculus with 12 samples.

How the data were processed

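Gene expression was measured in E14 mouse embryonic stem cells with single-colour Illumina bead arrays that carry 45281 probes. The 12 arrays form 4 groups of 3, untreated cells (0 h) and cells exposed to 50 nM panobinostat for 2 h, 6 h and 18 h. Per the labels' protocols, cells grew on gelatin with serum and LIF, RNA was purified with Trizol and spin columns, and biotin-labelled cRNA was hybridized. Group and replicate number of each array were taken from the labels, and 0 columns remained unassigned.

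The deposited table of unnormalized values holds, per the file headers, a signal and a detection p-value for every probe on every array. The signal columns are intensities on a linear scale that the authors exported with GenomeStudio, per the submitters' processing notes, which give no version, and the background setting is not given in the sources used here. From the values, no normalization or background subtraction had been applied to the signals as deposited. The detection p-value that the authors deposited falls as the signal rises, in steps that fit 936 negative control beads per array. A second deposited table holds the authors' normalized intensities, which from the values were quantile normalized on a linear scale: column medians lie between 117.3 and 117.4, and each column has a Spearman correlation of 1 with its own signal column and at most 0.887 with any other. The analysis started from the unnormalized signals, because the background could then be corrected from the detection p-values, and the authors' normalized values served as an alternative.

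Array annotation gave 34885 probes with 1 gene, 18 with several and 10378 without a named gene. Of these, 34807 were brought to current symbols through their gene identifier in the RefSeq gene table of GRCm38.p6. The files name no genome build, so no coordinates are printed. Signals were background corrected with the normexp model of limma (version 3.58.1, in R 4.3.3), with the background estimated from the detection p-values and an offset of 16, then quantile normalized and log2 transformed. Probes with a detection p-value under 0.05 on at least 3 of the 12 arrays were kept, 20029 in all, of which 17029 had 1 gene and 3000 had none. Each of 11445 genes, of 19057 on the array, was represented by its probe with the highest mean over all arrays, chosen among several kept probes for 3947 genes. For the 126 genes named by rule, 67 further probes were kept. Where the gene changed, 8 of 10 of them at 2 h, 26 of 55 at 6 h and 27 of 63 at 18 h read less than 0.5 of its log2 change. Their direction was opposite to a changed gene for Cldn10 at 2 h, Esrrb at 6 h, and Ep300 and Sesn2 at 18 h.

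A linear model with 1 mean per group was fitted to all 12 arrays with limma, and its moderated test with Benjamini-Hochberg adjustment over all genes gave the adjusted p-values, with 0.05 as the threshold and all tests 2-sided. The comparisons were 2 h, 6 h and 18 h against 0 h, 6 h against 2 h, 18 h against 6 h, and a moderated F test over the 4 groups. The median SE of a log2 change was 0.200 and the number of arrays limits this precision. On simulated data for 6 h against 0 h with 11445 genes, 4 of 67 genes changed by 0.5 on the log2 scale were recovered, 49 of 67 changed by 1 and 66 of 66 changed by 2, with 6 false calls. Far fewer genes changed in this simulation than the 3591 called in the real comparison. The adjustment is looser where more genes change, so these recoveries are not those of the real comparison. Of 200 random lists without change, 10 had a set test p under 0.05. Genes were simulated independently of each other, so this does not test how correlated genes affect the set test.

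Before the data were examined, 31 gene lists were fixed from general knowledge, together with the comparisons, the tests, the rule for named genes and the alternatives. The lists were core pluripotency, naive pluripotency, formative and primed pluripotency, primitive streak and mesoderm, endoderm, trophectoderm and placenta, neural and neuronal, 2-cell-like state, germline, Hox genes, p53 targets, CDK inhibitors, DNA replication, mitosis, apoptosis regulators, histone deacetylases, HDAC complex partners, histone acetyltransferases and BET readers, Polycomb subunits, DNA methylation machinery, histone genes with polyadenylated transcripts, genes known to respond to HDAC inhibitors in other cells, ribosome biogenesis and MYC targets, glycolysis, cholesterol synthesis, heat shock and unfolded protein response, immediate early genes, LIF, FGF, BMP and Nodal signalling targets, imprinted genes, and, as markers of other cell types, fibroblasts and blood and endothelium. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within each comparison. The list of genes known to respond to HDAC inhibitors was fixed without a direction for each member. Its median and set test therefore ask only for a common direction, at every time. Of 155 such tests 37 passed, and none of the 37 held when the correlation was estimated from the data. The rotation test fry was run beside it: its directional p-value asks whether the genes of a list move on balance in one direction, its mixed p-value whether they change in either direction, and neither compares the list with other genes. Median, mean and set test differed in sign for 3 lists at 2 h (neural and neuronal, fibroblasts, blood and endothelium), 1 at 6 h (fibroblasts), 3 at 18 h, 5 between 2 h and 6 h and 6 between 6 h and 18 h, none of them among the 37.

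The rule for named genes took, for each time against 0 h, the 5 largest rises and 5 largest falls among genes past the threshold with a detection p-value under 0.01 on all 3 arrays of the higher group and with all 3 treated arrays on the same side of all 3 control arrays. It added the fixed genes Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Myc, Cdkn1a, H1f0, Hdac1, Hdac2 and Hdac3, up to 2 members of each list past the threshold in each direction at 18 h (and at 2 h or 6 h where the list passed there), and the 3 largest rises and falls between successive times. Where no array of a group detected a gene, its fold is a lower bound: the mean of the other group was compared with the mean, over the arrays of the undetected group, of the higher of the gene's own value and the lowest value of any detected probe on that array. With all undetected groups at this bound, the medians of the 37 lists that passed moved by at most 0.17 and none changed sign.

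Comparisons against 0 h share the same 3 control arrays, so correlations between them were set beside 20 simulations of unchanged groups. Overlaps were set beside those of independent lists, which do not account for the shared controls. Whether replicate numbers pair the arrays was checked from the deviations of each array from its group mean. Same-numbered arrays correlated over 0.1 in all 3 pairs between 0 h and 2 h (0.332, 0.355 and 0.319), 0 h and 6 h (0.180, 0.271 and 0.398), 2 h and 6 h (0.311, 0.350 and 0.491) and 6 h and 18 h (0.146, 0.181 and 0.342). Replicate 1 fell short between 0 h and 18 h (0.0666, beside 0.259 and 0.418) and between 2 h and 18 h (0.0698, beside 0.230 and 0.210). The pairing therefore comes from the data, not from the labels, and a model with the replicate number as a block was fitted beside the one without it.

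The alternatives were no background correction, an offset of 50, scaling to the 75th percentile, cyclic loess, the authors' normalized values, no filter on dim probes, a strict filter (detection p-value under 0.01 on all 3 arrays of at least 1 group), the mean of a gene's probes, a variance model with trend and robust fit, array weights, only the groups compared, the replicate block, leaving out each array in turn, camera with an estimated correlation, and fry.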

Results

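The transcriptome of mouse embryonic stem cells was measured before and during exposure to panobinostat (LBH589), an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from histones. The cells were of the E14 line, which comes from the inner cell mass of a 129/Ola mouse embryo and was kept here in serum with the cytokine LIF and without feeder cells. Cells were left untreated (0 h) or exposed to 50 nM of the drug for 2 h, 6 h or 18 h, and 3 Illumina bead arrays were measured per group, 12 in all. Between 16813 and 18111 of 45281 probes were detected per array, and the mean signal of an array lay between 307.3 and 482.7 units. After filtering, 11445 genes were tested with limma over all 12 arrays. Values are given below as normalized log2 signal with the standard deviation (SD) over the 3 arrays of a group, or as log2 change with its standard error (SE), and p-values are adjusted over all genes tested. The labels do not say whether the 3 arrays of a group come from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The labels also name no vehicle control and no untreated cells at 2 h, 6 h or 18 h. Effects of the drug therefore cannot be told apart from those of handling and time in culture.

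Of the 11445 genes, 395 changed at 2 h (273 higher, 122 lower), 3591 at 6 h (2033 higher, 1558 lower) and 4200 at 18 h (2400 higher, 1800 lower) at an adjusted p under 0.05. These were 3.45%, 31.4% and 36.7% of the genes tested. A change of at least 2-fold was seen for 174, 1284 and 1642 of them, and for 42, 447 and 601 without background correction. A single test for any change over the 4 times called 5045 genes (44.1%). Arrays of a group correlated at 0.971 to 0.989 across genes and arrays of different groups at 0.889 to 0.984. The first principal component, with 51.6% of the variance, placed the 0 h and 2 h arrays on one side and the 6 h and 18 h arrays on the other.

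**Figure D1:**
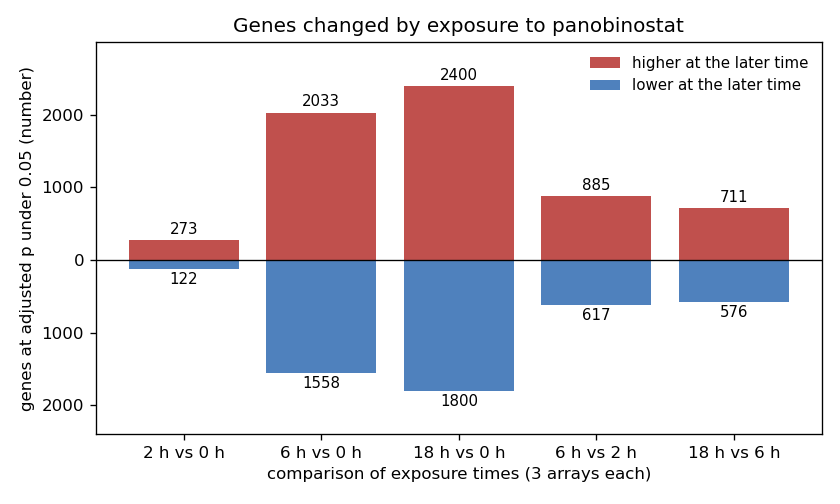
Number of genes with an adjusted p under 0.05 in each comparison of exposure times (x axis, 3 arrays per time); red bars above the line count genes higher at the later time and blue bars below it genes lower at the later time. The count grew from 273 higher and 122 lower at 2 h to 2400 higher and 1800 lower at 18 h.

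The comparison of 2 h with 0 h asks which transcripts differed after the first hours of exposure. Among those that rose were immediate early genes, many of them transcription factors, which cells switch on without new protein synthesis. Fos, a subunit of the AP-1 factor, went from 7.42 ± 0.71 to 10.21 ± 0.22 (SD, n = 3), a log2 change of 2.79 (SE 0.34, adjusted p = 0.00265). Egr1, a zinc finger factor induced by growth signals, went from 10.62 ± 0.54 to 13.19 ± 0.31, a log2 change of 2.57 (SE 0.27, adjusted p = 0.00105). Its relative Egr2 was detected on no 0 h array and on all 3 arrays at 2 h, at least 3.97-fold higher (measured means 4.70 and 7.04, adjusted p = 0.00364). Egr4 rose by 3.17 (SE 0.54, adjusted p = 0.008), with 1 of 3 arrays detecting it at 0 h, and Rem2, a small GTPase of excitable cells, rose by 2.14 (SE 0.37, adjusted p = 0.00907).

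Among 15 tested immediate early genes 6 rose, none fell and 9 did not pass at 2 h, with 7 rising when adjusted over the list alone and a median log2 change of 0.87. The set test gave an adjusted p = 5.92e-08 for this list, and adjusted p = 0.419 with an estimated correlation. Of the 16 genes of glycolysis 1 fell and 15 did not pass, also 1 when adjusted over the list alone, with a median of -0.35. The set test gave an adjusted p = 0.000392, and adjusted p = 0.932 with an estimated correlation and 0.175 with fry. The member that fell was Pfkp, the platelet isoform of phosphofructokinase, which changed by -0.84 (SE 0.18, adjusted p = 0.0196). Its adjusted p was 0.084 without 0 h replicate 3, and 0.0859, 0.0645 and 0.0514 without 2 h replicates 1, 2 and 3.

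The genes with the largest falls at 2 h were Ubap1l at -2.02 (SE 0.27, adjusted p = 0.0042), Bhlhe40 at -1.85 (SE 0.42, adjusted p = 0.0308), Kbtbd13 at -1.80 (SE 0.30, adjusted p = 0.00681) and the small nucleolar RNA Snora65 at -1.72 (SE 0.33, adjusted p = 0.0126, its second probe -0.58). Bhlhe40, a repressor tied to the circadian clock, did not pass without 0 h replicate 2 (0.0883), 0 h replicate 3 (0.0735), 2 h replicate 1 (0.129) or 2 h replicate 3 (0.0904), without the filter on dim probes (0.0673), or when only the groups compared were fitted (0.0507). Snora65 did not pass without 0 h replicate 3 (0.0506) or 2 h replicate 1 (0.0633). Ovgp1, an oviductal glycoprotein, was detected on all 3 arrays at 0 h and on none at 2 h, at least 2.77-fold lower (means 6.53 and 4.95, adjusted p = 0.0135), and did not pass without 2 h replicate 1 (0.0517) or 3 (0.0566). Nupr1 and Trib3, both targets of the amino acid and endoplasmic reticulum stress response, fell by 1.46 (SE 0.25, adjusted p = 0.00842) and by 1.1 (SE 0.18, adjusted p = 0.00603).

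Of the pluripotency genes few passed at 2 h. None of 13 core pluripotency genes passed (median -0.16, adjusted p = 0.287) and 1 of 17 naive pluripotency genes fell (median -0.29, adjusted p = 0.103). The set test called the core list without 0 h replicate 2 (0.00995, median -0.33), and the naive list without 0 h replicate 2 (0.00597, median -0.46) or 2 h replicate 3 (0.00113, median -0.49). Pou5f1, which encodes the pluripotency factor Oct4, changed by -0.33 (SE 0.17, adjusted p = 0.35) and Nanog by -0.50 (SE 0.33, adjusted p = 0.481). Sox2, their partner factor, changed by -1.09 (SE 0.32, adjusted p = 0.0828, its second, dimmer probe -1.53). Sox2 passed with replicate numbers as a block (0.0395) or with the mean of its probes (0.0272). Genes known to respond to such inhibitors in other cells had 2 of 15 higher, 4 when adjusted over the list alone, a median of 0.37 and an adjusted p = 0.051. They passed with the block (0.0438), with other scalings or backgrounds (0.0353 to 0.0452), without 0 h replicate 2 (0.0182), 2 h replicate 3 (0.039) or 18 h replicates 1 (0.0456) or 2 (0.0456), and with fry (0.00333). Cholesterol synthesis genes had 1 of 15 higher, a median of 0.34 and an adjusted p = 0.051. They passed with the block (0.0438), with other scalings, backgrounds or no filter (0.0151 to 0.0435), and without 0 h replicate 3 (0.0109) or 2 h replicates 1 (0.00231) or 2 (0.00183). Germline genes (median -0.23, adjusted p = 0.139) passed without 0 h replicate 2 (0.0182) or 2 h replicate 3 (0.0414).

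The count at 2 h was the most dependent on single arrays. It was 135 without 0 h replicate 3 and 147, 173 and 155 without 2 h replicates 1, 2 and 3, and 763 (474 higher, 289 lower) with replicate numbers as a block. The lower genes numbered 28, 34, 44 and 34 without these arrays, 78 and 80 without 6 h replicates 1 and 2, and 65 with 75th percentile scaling.

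The comparison of 6 h with 0 h asks how far the response had spread within the same day. Nanog, a homeobox factor of the naive state, went from 12.66 ± 0.15 to 10.45 ± 0.20 (SD, n = 3), and fell by 2.20 (SE 0.33, adjusted p = 0.000313). Klf4, a Krüppel-like factor that LIF maintains, fell by 2.00 (SE 0.24, adjusted p = 8.51e-05), the nuclear receptor Esrrb by 1.69 (SE 0.28, adjusted p = 0.000595) and the naive marker Zfp42 (Rex1) by 2.34 (SE 0.32, adjusted p = 0.000204). A second, dimmer probe of Esrrb read 0.14 at 6 h and -0.38 at 18 h.

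Of 17 naive pluripotency genes 11 fell, none rose and 6 did not pass at 6 h, also 11 when adjusted over the list alone, with a median of -1.53 (adjusted p = 1.46e-05, and adjusted p = 0.515 with an estimated correlation). Nr5a2, a nuclear receptor that binds the Pou5f1 promoter, fell by 2.60 (SE 0.36, adjusted p = 0.000202). Of 13 core pluripotency genes 9 fell and 4 did not pass, 10 when adjusted over the list alone, with a median of -1.17 (adjusted p = 1.46e-05, and adjusted p = 0.515 with an estimated correlation). Gdf3, a ligand of the TGF-beta family, fell by 3.48 (SE 0.35, adjusted p = 2.84e-05) and Tdgf1, a Nodal co-receptor, by 1.76 (SE 0.26, adjusted p = 0.000273).

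Pou5f1 stood near the threshold at 6 h, from 10.55 ± 0.28 to 10.04 ± 0.08, a change of -0.50 (SE 0.17, adjusted p = 0.0425). Its adjusted p was 0.0743 and 0.17 without 0 h replicates 2 and 3, 0.0507 and 0.0559 without 2 h replicates 1 and 2, 0.077, 0.121 and 0.0837 without 6 h replicates 1, 2 and 3, and 0.0515 without 18 h replicate 2. It was 0.0654 with only the groups compared and 0.0595 with array weights. Sox2 changed by -1.17 (SE 0.32, adjusted p = 0.0138, its second, dimmer probe -1.67), and by less than the threshold requires without 0 h replicate 3 (0.0655).

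Beyond Gdf3, the largest log2 changes downward at 6 h were -3.53 for Otx2, a homeobox factor of the formative state and the forebrain (SE 0.39, adjusted p = 5.19e-05), and -3.28 for the growth factor Fgf17 (SE 0.23, adjusted p = 5.34e-06). Next came Ubap1l at -3.23 (SE 0.27, adjusted p = 1.18e-05, 1 of 3 arrays detecting it at 6 h) and Gli2, a transcription factor of Hedgehog signalling, at -3.20 (SE 0.31, adjusted p = 2.79e-05, its second, dimmer probe -0.28). The largest rises were those of 6430548M08Rik at 4.15 (SE 0.38, adjusted p = 1.67e-05), the phosphatase Dusp2 at 4.12 (SE 0.48, adjusted p = 7.01e-05), the natriuretic peptide gene Nppb at 4.02 (SE 0.35, adjusted p = 1.36e-05), Nrip3 at 4.02 (SE 0.47, adjusted p = 7.77e-05) and Egr4 at 3.89 (SE 0.54, adjusted p = 0.000204). At 0 h these were detected on 1, 2, 1, 2 and 1 of 3 arrays, in that order.

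Of 15 immediate early genes tested at 6 h, 8 rose and 7 did not pass, 9 rising when adjusted over the list alone, with a median of 1.34 (adjusted p = 1.42e-05, and adjusted p = 0.515 with an estimated correlation). Fos stood 3.45 above 0 h (SE 0.34, adjusted p = 2.84e-05) and Egr1 3.11 above it (SE 0.27, adjusted p = 1.36e-05). Of 15 genes of cholesterol synthesis 7 rose and 8 did not pass, 12 rising when adjusted over the list alone, with a median of 0.84 (adjusted p = 0.00124, and adjusted p = 0.641 with an estimated correlation). Hsd17b7, a sterol reductase, rose by 1.57 (SE 0.20, adjusted p = 0.000141, its second probe 0.28) and Idi1, which isomerizes isopentenyl diphosphate, by 1.26 (SE 0.22, adjusted p = 0.000841).

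Of the lists of chromatin genes 2 passed at 6 h, both with lower medians. Of 14 histone acetyltransferases and BET readers 6 fell and 8 did not pass, 7 falling when adjusted over the list alone, with a median of -0.59 (adjusted p = 0.00594, and adjusted p = 0.515 with an estimated correlation). The acetyltransferases Kat7 and Ep300 (p300) changed by -1.2 (SE 0.15, adjusted p = 0.000124) and -1.13 (SE 0.27, adjusted p = 0.00663, further probes of Ep300 -0.34 and -0.07). Of 23 Polycomb subunits, parts of complexes that silence developmental genes, 7 fell, 3 rose and 13 did not pass, 8 and 3 when adjusted over the list alone. Their median was -0.46, or -0.39 with undetected members at their bound (adjusted p = 0.0164, and adjusted p = 0.515 with an estimated correlation), and the list did not pass without 0 h replicate 3 (0.0534). Phc1 fell by 1.34 (SE 0.15, adjusted p = 4.72e-05) and Bcor by 1.2 (SE 0.26, adjusted p = 0.00399), while Phc2 rose by 0.81 (SE 0.16, adjusted p = 0.00244).

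Glycolysis genes had 6 of 16 lower and 10 not passing at 6 h, also 6 when adjusted over the list alone, with a median of -0.39 (adjusted p = 0.00177, and adjusted p = 0.515 with an estimated correlation). Pdk1, a kinase that holds pyruvate back from oxidation in the mitochondrion, fell by 1.35 (SE 0.23, adjusted p = 0.000853) and Pfkp by 1.05 (SE 0.18, adjusted p = 0.00069). Of 23 genes of ribosome biogenesis and MYC targets 6 fell, 1 rose and 16 did not pass, 7 and 1 when adjusted over the list alone, with a median of -0.22 (adjusted p = 0.0454, and adjusted p = 0.642 with an estimated correlation). The nucleolar protein genes Gnl3 and Nop56 fell by 1.39 (SE 0.24, adjusted p = 0.000828, 1 of 3 arrays detecting Gnl3 at 6 h) and by 1.18 (SE 0.24, adjusted p = 0.00249). This list did not pass with the block (0.0522), with only the groups compared (0.0601), or without 0 h replicate 1 (0.241), 0 h replicate 3 (0.11), 6 h replicate 2 (0.0695), 18 h replicate 1 (0.054) or 18 h replicate 2 (0.0591). Its median was -0.13 and -0.15 without 0 h replicates 1 and 3, and -0.22 to -0.24 in the other settings just named. Mitosis genes (median -0.20, adjusted p = 0.0532) passed with the block (0.0428), with other scalings, backgrounds or no filter (0.0264 to 0.0489), and without 0 h replicate 2 (0.0147) or 6 h replicate 3 (0.0207). HDAC complex partners (median -0.39, adjusted p = 0.0522) passed with other backgrounds, cyclic loess or no filter (0.0178 to 0.0489), and without 0 h replicate 2 (0.035), 2 h replicates 2 (0.0479) or 3 (0.0498) or 6 h replicate 3 (0.016).

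Further lists passed at 6 h under other settings. With fry these were CDK inhibitors (median 0.59, adjusted p = 0.00553), DNA replication (-0.16, 0.0279), apoptosis regulators (0.41, 0.00553), HDAC complex partners (0.0111), histone genes (0.12, 0.033) and genes known to respond to such inhibitors in other cells (0.52, 0.000489). Ribosome biogenesis did not pass with fry (0.118). CDK inhibitors passed without the filter on dim probes (0.0242), and histone genes without that filter (0.0295) or 6 h replicate 1 (0.0479). The p53 targets passed without the filter (0.0463), 0 h replicate 3 (0.0232), 2 h replicate 2 (0.0471) or 6 h replicate 1 (0.0479).

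The comparison of 18 h with 0 h asks what state the cells had reached after the longest exposure. Pou5f1 had now fallen from 10.55 ± 0.28 to 8.26 ± 0.23 (SD, n = 3), by 2.28 (SE 0.17, adjusted p = 2.2e-06). Nanog fell by 2.29 (SE 0.33, adjusted p = 0.00018), Klf4 by 2.16 (SE 0.24, adjusted p = 3.12e-05), Esrrb by 2.54 (SE 0.28, adjusted p = 2.86e-05) and Zfp42 by 2.45 (SE 0.32, adjusted p = 0.000111). Of 17 naive pluripotency genes 13 fell, none rose and 4 did not pass, and of 13 core pluripotency genes 11 fell, none rose and 2 did not pass. Sox2 changed least of the 6 factors, from 10.00 ± 0.50 to 9.01 ± 0.78, by -0.99 (SE 0.32, adjusted p = 0.0271, its second, dimmer probe -1.51). It did not pass without 0 h replicate 1 (0.0559), 0 h replicate 3 (0.121) or 18 h replicate 1 (0.11), without the filter on dim probes (0.056), or with only the groups compared (0.0818).

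**Figure D2:**
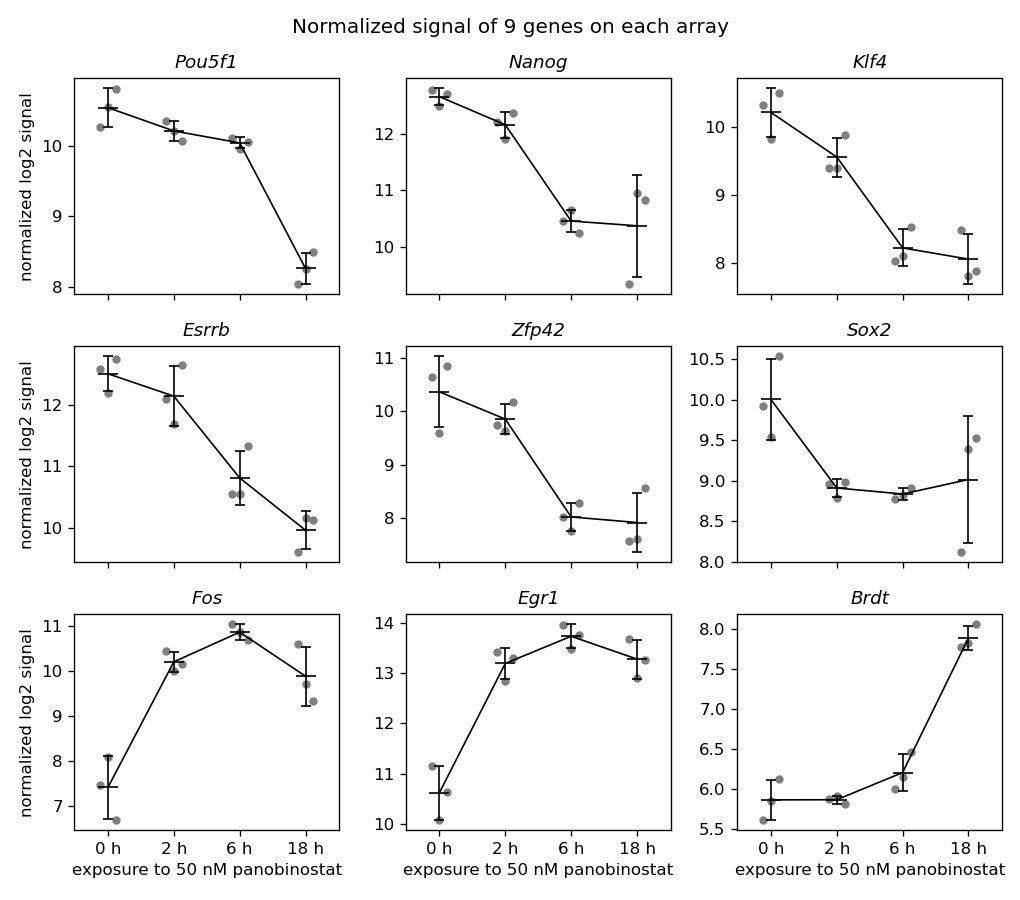
Normalized log2 signal (y axes, which differ between panels and do not start at 0) of 9 genes at 0, 2, 6 and 18 h of exposure to 50 nM panobinostat (x axis); grey points are single arrays, black marks and bars the mean and SD of 3 arrays, joined by lines. Pou5f1 went from 10.55 to 8.26 and Nanog from 12.66 to 10.37 between 0 h and 18 h, with 1 of the 3 arrays at 18 h well below the other 2 for Nanog and Sox2, while Fos and Egr1 stood above 0 h at every later time and Brdt rose at 18 h.

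The naive list had a median of -1.68 at 18 h (adjusted p = 8.42e-08, and adjusted p = 0.277 with an estimated correlation), with 13 genes lower also when adjusted over the list alone. Jam2, a cell adhesion molecule, fell by 3.43 (SE 0.26, adjusted p = 2.19e-06, 5 further probes -0.41 to -3.11) and the T-box factor Tbx3 by 2.91 (SE 0.27, adjusted p = 9.58e-06, 3 further probes -0.54 to -3.03). The core list had a median of -1.56 (adjusted p = 3.93e-07, and adjusted p = 0.277 with an estimated correlation), with 11 lower and 1 higher when adjusted over the list alone. Gdf3 fell by 4.39 (SE 0.35, adjusted p = 2.61e-06) and Utf1, a chromatin-bound factor of pluripotent cells, by 2.45 (SE 0.21, adjusted p = 5.6e-06). Of 10 formative and primed pluripotency genes 4 fell and 6 did not pass, also 4 when adjusted over the list alone, with a median of -0.39 (adjusted p = 0.0232, and adjusted p = 0.457 with an estimated correlation). Otx2 fell by 3.03 (SE 0.39, adjusted p = 8.41e-05) and the growth factor gene Fgf15 by 1.99 (SE 0.22, adjusted p = 3.33e-05). That list did not pass without 0 h replicate 1 (0.0712) or with the strict detection filter (0.0739).

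Of 22 germline genes tested 12 rose at 18 h, none fell and 10 did not pass, 13 rising and 1 falling when adjusted over the list alone, with a median of 0.69, or 0.64 with undetected members at their bound (adjusted p = 0.00164, and adjusted p = 0.277 with an estimated correlation). Brdt, a bromodomain protein of spermatocytes, went from 5.86 ± 0.25 to 7.89 ± 0.15, a rise of 2.02 (SE 0.17, adjusted p = 4.34e-06). Tex13b, a testis gene on the X chromosome, was detected on none of the 0 h arrays and all 3 at 18 h, at least 2.39-fold higher (means 4.56 and 6.31, adjusted p = 0.000695). Further members that rose lay outside the rule for named genes and were chosen after their values were seen: the RNA-binding germ cell gene Dazl rose by 1.32 (SE 0.31, adjusted p = 0.00529), Taf7l by 1.66 (adjusted p = 0.000566) and Sycp2 of the synaptonemal complex by 1.2 (adjusted p = 9.03e-05).

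Of 8 CDK inhibitors 6 rose at 18 h, 1 fell and 1 did not pass, 7 and 1 when adjusted over the list alone, with a median of 0.92 (adjusted p = 0.0201, and adjusted p = 0.277 with an estimated correlation). Cdkn1c (p57) rose by 1.84 (SE 0.31, adjusted p = 0.000551) and Cdkn2b (p15) by 1.59 (SE 0.17, adjusted p = 2.84e-05), while Cdkn1b (p27) was detected on all 3 arrays at 0 h and on none at 18 h, at least 2.49-fold lower (means 6.32 and 4.73, adjusted p = 0.000469). Cdkn1a (p21), a gene widely induced by such inhibitors, was the member that did not pass. Its log2 changes were 0.49 at 2 h, 0.43 at 6 h and 0.49 at 18 h (SE 0.20, adjusted p = 0.213, 0.116 and 0.0703). A further Cdkn1a probe read 0.39, 0.27 and 0.41 at these times, and another, dimmer probe 0.31, -0.17 and -0.21. Of 27 DNA replication genes 14 fell, none rose and 13 did not pass, 14 lower and 1 higher when adjusted over the list alone, with a median of -0.45 (adjusted p = 0.000232, and adjusted p = 0.277 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell by 1.36 (SE 0.18, adjusted p = 0.000115) and the licensing factor Cdt1 by 0.92 (SE 0.14, adjusted p = 0.000261). Of 22 mitosis genes 10 fell, none rose and 12 did not pass, 11 lower when adjusted over the list alone, with a median of -0.52 (adjusted p = 0.00128, and adjusted p = 0.457 with an estimated correlation), among them the mitotic kinase Plk1, which fell by 0.81 (SE 0.18, adjusted p = 0.00298).

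Of the drug's own targets, the histone deacetylases, 3 of 10 tested rose, 1 fell and 6 did not pass at 18 h, the same counts when adjusted over the list alone (median 0.17, adjusted p = 0.724). Hdac2 was at 12.18 ± 0.07 and 12.28 ± 0.04, a log2 change of 0.10 (SE 0.13, adjusted p = 0.574, its second probe -0.54). Hdac3 changed by 0.43 at 6 h (SE 0.15, adjusted p = 0.0444) and 0.55 at 18 h (adjusted p = 0.0117). It did not pass at 18 h without 0 h replicate 1 (0.0542). At 6 h it did not pass without 0 h replicates 1 (0.156) and 3 (0.0915), 2 h replicates 2 (0.0548) and 3 (0.0544) or 6 h replicates 1 (0.11), 2 (0.0965) and 3 (0.087), with 75th percentile scaling (0.0982), or with only the groups compared (0.0698). Hdac4 fell by 1.21 (SE 0.16, adjusted p = 0.000125). Hdac1, the linker histone gene H1f0 and Myc, fixed in advance as genes to report, were not analysed here: Hdac1 and H1f0 had no probe of that name, and neither of 2 Myc probes passed the detection filter.

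Of the other lists of chromatin genes 3 passed at 18 h, all with lower medians. Of 21 HDAC complex partners 11 fell, 2 rose and 8 did not pass, 12 and 2 when adjusted over the list alone, with a median of -0.60, or -0.47 with undetected members at their bound (adjusted p = 0.000795, and adjusted p = 0.277 with an estimated correlation). Mta3, a subunit of the NuRD complex, fell by 2.18 (SE 0.22, adjusted p = 1.76e-05). Of 14 histone acetyltransferases and BET readers 8 fell and 6 did not pass, 9 lower when adjusted over the list alone, with a median of -0.65 (adjusted p = 0.000561, and adjusted p = 0.277 with an estimated correlation). Kat6b fell by 1.53 (SE 0.20, adjusted p = 0.000109, further probes -0.23 and -0.75), and Kat2b was detected on none of the 18 h arrays, at least 1.96-fold lower (means 5.97 and 4.74, adjusted p = 0.00838). Of 23 Polycomb subunits 8 fell, 2 rose and 13 did not pass, 9 and 2 when adjusted over the list alone, with a median of -0.38, or -0.21 with undetected members at their bound (adjusted p = 0.0132, and adjusted p = 0.319 with an estimated correlation). Phc1 fell by 1.83 (SE 0.15, adjusted p = 2.61e-06) and Phc2 rose by 1.18 (SE 0.16, adjusted p = 0.000145). Of 11 genes of the DNA methylation machinery 4 fell and 7 did not pass, also 4 when adjusted over the list alone (median -0.00, mean -0.40, adjusted p = 0.344), with Tet1, which oxidizes methylcytosine, at -3.52 (SE 0.52, adjusted p = 0.000232).

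Ribosome biogenesis genes and MYC targets had 11 of 23 lower and 12 not passing at 18 h, also 11 when adjusted over the list alone, with a median of -0.46 (adjusted p = 0.00215, and adjusted p = 0.514 with an estimated correlation), Nop56 falling by 1.60 (SE 0.24, adjusted p = 0.000252). Immediate early genes had 10 of 15 higher and 5 not passing, also 10 when adjusted over the list alone, with a median of 1.60 (adjusted p = 0.000151, and adjusted p = 0.319 with an estimated correlation). Egr1 stood 2.65 above 0 h (SE 0.27, adjusted p = 1.79e-05) and Fos 2.47 above it (SE 0.34, adjusted p = 0.000136).

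**Figure D3:**
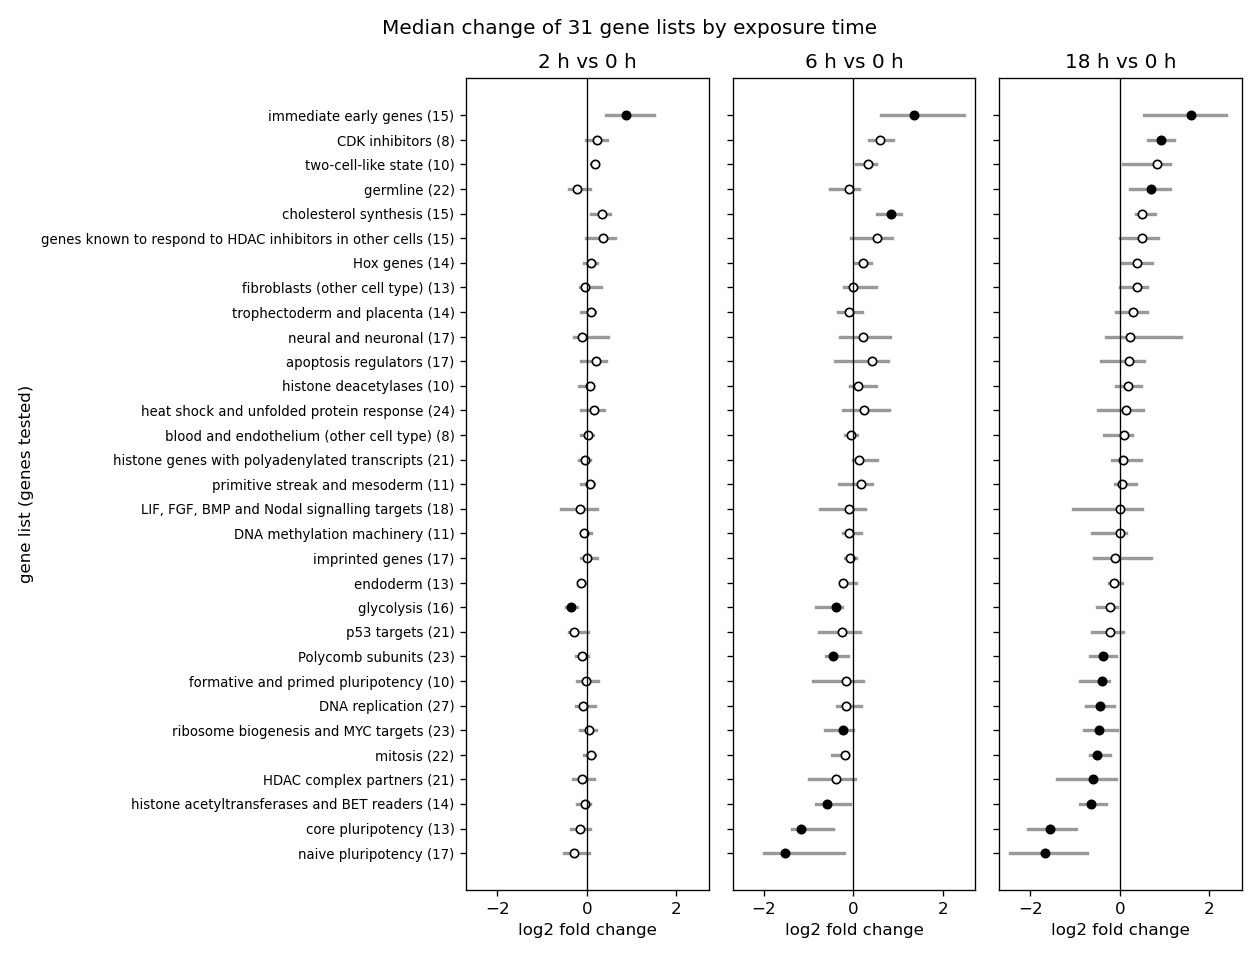
Median log2 change against 0 h (x axis) of each of 31 gene lists (y axis) at 2, 6 and 18 h; points are medians over the list's tested genes, grey bars their interquartile range, and filled points mark lists with a set test adjusted p under 0.05 at the preset correlation. The naive pluripotency list lies at -0.29, -1.53 and -1.68 and the immediate early genes at 0.87, 1.34 and 1.60 in the order of the times.

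The single genes with the largest changes at 18 h included several that untreated cells barely expressed. Cldn10, a tight junction protein, Dmkn, a secreted epidermal protein, AU015228 and Oas1e, of the oligoadenylate synthetase family, were detected on no 0 h array and on all 3 arrays at 18 h. They were at least 16.6-fold, 18.7-fold, 19.5-fold and 18.4-fold higher (means 4.53 and 9.10, 4.87 and 9.27, 4.35 and 9.33, 4.53 and 9.25, adjusted p = 3.24e-09, 4.18e-06, 2.36e-07 and 2.83e-05). A second kept probe of AU015228 read a change of 1.11, and further probes of Cldn10 read 1.21 and 2.48. Nppb rose by 4.81 (SE 0.35, adjusted p = 1.88e-06). After Gdf3 the genes that moved furthest down were Lefty1, a Nodal antagonist, which fell by 3.88 (SE 0.53, adjusted p = 0.000135), Nupr1, which fell by 3.53 (SE 0.25, adjusted p = 1.79e-06), and Tet1. Ubap1l was detected on all 3 arrays at 0 h and on none at 18 h, at least 8.44-fold lower (means 8.08 and 4.59, adjusted p = 2.58e-06).

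No list of markers of differentiated lineages passed with camera at 18 h against 0 h, although single members rose. Of 11 primitive streak and mesoderm genes 2 rose, also 2 when adjusted over the list alone (median 0.04, adjusted p = 0.722), with the caudal factor Cdx1 up by 1.68 (SE 0.22, adjusted p = 0.000114, 2 of 3 arrays detecting it at 0 h). Of 13 endoderm genes 3 rose, also 3 when adjusted over the list alone. That list's median was -0.13 and its set test pointed down (adjusted p = 0.995), while its mean was 0.12. The receptor gene Pdgfra was detected on no 0 h array, at least 2.4-fold higher at 18 h (means 4.51 and 6.32, adjusted p = 3.11e-06). Of 14 trophectoderm and placenta genes 4 rose, also 4 when adjusted over the list alone (median 0.29, or 0.10 with undetected members at their bound, adjusted p = 0.328). Cdx2, the factor that specifies trophectoderm, rose by 1.92 (SE 0.30, adjusted p = 0.000332). Of 17 neural and neuronal genes 7 rose and 3 fell, the same counts when adjusted over the list alone (median 0.22, adjusted p = 0.301). This list passed with fry (0.0166), which does not compare a list with other genes. The synaptic vesicle protein gene Syt1 rose by 2.20 (SE 0.28, adjusted p = 9.45e-05, its second probe 0.63, 2 of 3 arrays detecting it at 0 h) and the neuronal factor gene Neurod1 stood at -1.22 (SE 0.21, adjusted p = 0.000545).

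Of 14 Hox genes 4 rose at 18 h, 3 when adjusted over the list alone (median 0.39, or 0.19 with undetected members at their bound, adjusted p = 0.124), Hoxd8 by 1.57 (SE 0.21, adjusted p = 0.000113, 2 of 3 arrays detecting it at 0 h), and the list passed with fry (0.0166). Of 10 genes of the 2-cell-like state, a rare state of stem cells that express genes of the early embryo, 6 rose and 1 fell, the same counts when adjusted over the list alone (median 0.83, adjusted p = 0.195). Pramel16 rose by 1.44 (SE 0.24, adjusted p = 0.000557). Of 17 imprinted genes 3 rose and 5 fell, the same when adjusted over the list alone (median -0.10, adjusted p = 0.411), with Cdkn1c the largest rise and the adaptor gene Grb10, at -2.39, the largest fall (SE 0.19, adjusted p = 2.58e-06, its second probe -0.97). Of 18 targets of LIF, FGF, BMP and Nodal signalling 4 rose and 6 fell, the same when adjusted over the list alone, with a median of 0.01 against a mean of -0.34 and a set test that pointed down (adjusted p = 0.259, and 0.0166 with fry). Id1, a BMP target, rose by 2.10 (SE 0.40, adjusted p = 0.00131) and Lefty1 fell.

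Of 24 heat shock and unfolded protein response genes 5 rose and 6 fell at 18 h, the same when adjusted over the list alone, with a median of 0.14 and a mean of 0.16 against a set test that pointed down (adjusted p = 0.724). The chaperone gene Hspa1b rose by 3.49 (SE 0.37, adjusted p = 2.17e-05, 1 of 3 arrays detecting it at 0 h), and Trib3 fell by 1.74 (SE 0.18, adjusted p = 2.03e-05). Of 21 p53 targets 1 rose and 6 fell, the same when adjusted over the list alone (median -0.21, adjusted p = 0.0553). That list passed without 0 h replicate 3 (0.0138), 2 h replicate 2 (0.0398), 6 h replicate 1 (0.0407), 6 h replicate 3 (0.0436) or 18 h replicate 2 (0.0146), and with 75th percentile scaling (0.0228), cyclic loess (0.0394), no filter (0.0262) or fry (0.0305). Its median was -0.42 without 18 h replicate 2 and -0.21 to -0.31 in the other settings where it passed. Zmat3 fell by 1.62 (SE 0.23, adjusted p = 0.000185) and Sesn1 rose by 0.89 (SE 0.23, adjusted p = 0.00944). Of 17 apoptosis regulators 4 rose and 4 fell, 6 and 5 when adjusted over the list alone (median 0.20, adjusted p = 0.995). Of 15 genes known to respond to such inhibitors in other cells 6 rose and 3 fell, 8 and 3 when adjusted over the list alone (median 0.49, adjusted p = 0.195, and 0.000311 with fry). The metallothionein gene Mt2 rose by 1.98 (SE 0.19, adjusted p = 9.84e-06) and the cyclin gene Ccnd1 stood at -2.06 (SE 0.28, adjusted p = 0.000115). No direction was fixed for the members of this list, so its set test cannot tell whether they moved as in other cells.

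Of 21 histone genes with polyadenylated transcripts 5 rose and 2 fell at 18 h, the same when adjusted over the list alone (median 0.07, adjusted p = 0.561). The linker histone gene H1f10 rose by 1.86 (SE 0.15, adjusted p = 4.01e-06, its second probe 0.86). Glycolysis genes had 1 of 16 higher and 5 lower, the same when adjusted over the list alone (median -0.21, adjusted p = 0.0715), and passed without 0 h replicate 1 (0.0352) or 18 h replicate 2 (0.0236) and with 75th percentile scaling (0.00214), cyclic loess (0.0468) or no filter (0.0331). The glycolysis median was -0.57 with 75th percentile scaling and -0.15 to -0.31 in the other settings where the list passed. Cholesterol synthesis genes had 3 of 15 higher, also 3 when adjusted over the list alone (median 0.50, adjusted p = 0.0553). They passed with the block (0.0465), with 75th percentile scaling (0.0266), cyclic loess (0.0456) or no filter (0.013), with only the groups compared (0.0193), and without 0 h replicate 3 (0.0195), 2 h replicate 2 (0.0461) or 2 h replicate 3 (0.0186). Of the markers of other cell types, 3 of 13 fibroblast genes rose and 1 fell, the same when adjusted over the list alone (median 0.38, or 0.24 with undetected members at their bound, adjusted p = 0.411). Thy1 rose by 2.22 (SE 0.30, adjusted p = 0.000131) and Fn1 stood at -1.36 (SE 0.20, adjusted p = 0.000246). Of 8 blood and endothelium genes 1 rose and 2 fell, the same when adjusted over the list alone (median 0.09, or -0.01 with undetected members at their bound, adjusted p = 0.995). The globin gene Hba-a1 was detected on no 0 h array, at least 4.26-fold higher at 18 h (means 4.72 and 7.14, adjusted p = 2.95e-05).

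The responses at the 3 times overlapped. Of 273 genes raised at 2 h, among them Fos, Egr1 and Egr2, 253 (92.7%) were also raised at 6 h and 189 (69.2%) at 18 h. Of 122 lowered at 2 h, among them Nupr1 and Trib3, 103 (84.4%) were also lowered at 6 h and 80 (65.6%) at 18 h. The lists of 6 h and 18 h shared 1350 raised and 1070 lowered genes. Independent lists of these sizes would share 48.5 and 16.6 between 2 h and 6 h, 57.2 and 19.2 between 2 h and 18 h, and 426.3 and 245.0 between 6 h and 18 h. In all, 260 genes changed the same way at all 3 times (184 higher, 76 lower) and 17 went opposite ways at 2 of the times. The count of 260 was 89 without 0 h replicate 3 and 105, 124 and 117 without 2 h replicates 1, 2 and 3, and 470 with the block.

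Log2 changes correlated across genes at 0.713 between 2 h and 6 h, 0.428 between 2 h and 18 h, and 0.793 between 6 h and 18 h, where unchanged groups with the same controls gave 0.498 to 0.501. The covariances were 0.173, 0.117 and 0.386 against 0.0243, 0.0244 and 0.0245 simulated, differences of 0.148, 0.0923 and 0.362. Genes are not independent replicates, and part of the excess in the overlaps may come from the 3 shared control arrays, which were not split for these comparisons.

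The direct comparison of 6 h with 2 h asks whether the response itself moved on. Nanog fell by 1.71 (SE 0.33, adjusted p = 0.00599), Klf4 by 1.34 (SE 0.24, adjusted p = 0.00444) and Zfp42 by 1.83 (SE 0.32, adjusted p = 0.0043). Esrrb fell by 1.33 (SE 0.28, adjusted p = 0.0089) and did not pass with the mean of its probes (0.061). Pou5f1 changed by -0.17 (SE 0.17, adjusted p = 0.576) and Sox2 by -0.07 (SE 0.32, adjusted p = 0.91). The largest changes downward were -3.11 for Gdf3 (SE 0.35, adjusted p = 0.000428), -2.79 for Fgf17 (SE 0.23, adjusted p = 6.17e-05) and -2.79 for Gli2 (SE 0.31, adjusted p = 0.000428, its second probe -0.39). The largest rises were those of AU015228 at 2.64 (SE 0.27, adjusted p = 0.000299), Cldn10 at 2.62 (SE 0.16, adjusted p = 4.64e-06) and Rassf4 at 2.56 (SE 0.33, adjusted p = 0.00104). The second probe of AU015228 read 0.30 and the dimmer further probe of Cldn10 read 0.27. In all 885 genes rose and 617 fell, 498 of them at least 2-fold, or 113 at least 2-fold without background correction. The total of 1502 was 735, 835 and 974 without 2 h replicates 1, 2 and 3 and 540 and 770 without 6 h replicates 1 and 2.

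Of the lists, 10 passed between 2 h and 6 h. Core pluripotency had 7 of 13 lower, 9 when adjusted over the list alone (adjusted p = 2.54e-06, and adjusted p = 0.564 with an estimated correlation). Naive pluripotency had 10 of 17 lower, also 10 over the list alone (adjusted p = 2.54e-06, and adjusted p = 0.564 with an estimated correlation). Mitosis had 2 of 22 lower (adjusted p = 0.00165, and adjusted p = 0.687 with an estimated correlation), HDAC complex partners 4 of 21 (adjusted p = 0.0109, and adjusted p = 0.564 with an estimated correlation), and acetyltransferases and BET readers 3 of 14 (adjusted p = 0.00165, and adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone these were 3 lower, 9 lower with 1 higher, and 7 lower. Polycomb subunits had 2 of 23 lower and 1 higher, 4 and 1 adjusted over the list alone (adjusted p = 0.00729, and adjusted p = 0.564 with an estimated correlation). Ribosome biogenesis had 4 of 23 lower, 6 adjusted over the list alone (adjusted p = 0.00163, and adjusted p = 0.687 with an estimated correlation). Histone genes had 5 of 21 higher, also 5 adjusted over the list alone (adjusted p = 0.00672, and adjusted p = 0.687 with an estimated correlation), H1f10 rising by 1.54 (SE 0.15, adjusted p = 0.000299, its second probe 0.55). Cholesterol synthesis had 2 of 15 higher, 3 adjusted over the list alone (adjusted p = 0.00729, and adjusted p = 0.71 with an estimated correlation), and did not pass without 2 h replicates 1 (0.0852) or 2 (0.0956). Immediate early genes had 3 of 15 higher, also 3 adjusted over the list alone (adjusted p = 0.0215, and adjusted p = 0.71 with an estimated correlation), and did not pass without 2 h replicate 3 (0.1) or 6 h replicates 1 (0.0506) or 2 (0.0595). Formative and primed pluripotency passed without 2 h replicate 3 (0.00858) or 6 h replicate 2 (0.0461). With fry, mitosis, ribosome biogenesis and immediate early genes (each 0.136) and cholesterol synthesis (0.199) did not pass.

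Between 6 h and 18 h, Pou5f1 fell by 1.78 (SE 0.17, adjusted p = 0.000167), while Nanog changed by -0.08 (SE 0.33, adjusted p = 0.907) and Zfp42 by -0.10 (SE 0.32, adjusted p = 0.879). Esrrb changed by -0.85 (SE 0.28, adjusted p = 0.0639), which passed with the block (0.0135) or with the mean of its probes (0.0261). Bhlhe40, lower at 2 h and 6 h, rose by 2.81 (SE 0.42, adjusted p = 0.00198), to 10.61 ± 0.68 beside 10.23 ± 0.72 at 0 h. Ankrd37 rose by 2.57 (SE 0.28, adjusted p = 0.000263) and Oas1e by 3.67 (SE 0.51, adjusted p = 0.00127). The branched-chain aminotransferase gene Bcat1 fell by 2.08 (SE 0.18, adjusted p = 0.000167), the amino acid transporter gene Slc7a3 by 2.01 (SE 0.24, adjusted p = 0.000484) and Gm428 by 2.00 (SE 0.28, adjusted p = 0.00112). In all 711 genes rose and 576 fell, 411 of them at least 2-fold, or 105 at least 2-fold without background correction. With 75th percentile scaling 649 rose and 348 fell, and without 18 h replicate 1 the balance turned, with 565 higher and 589 lower. The total of 1287 was 605, 676 and 556 without 6 h replicates 1, 2 and 3, 635 without 18 h replicate 2, 875 (374 lower) without 18 h replicate 3, and 2112 (1172 higher, 940 lower) with the block.

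Of the lists, 5 passed between 6 h and 18 h. Germline genes had 12 of 22 higher, 14 when adjusted over the list alone, with a median of 0.85 (adjusted p = 1.04e-08, and adjusted p = 0.0607 with an estimated correlation), Brdt rising by 1.68 (SE 0.17, adjusted p = 0.000167). DNA replication had 5 of 27 lower, 7 when adjusted over the list alone (adjusted p = 0.00506, and adjusted p = 0.708 with an estimated correlation). Core pluripotency had 4 of 13 lower, 6 lower and 1 higher when adjusted over the list alone (adjusted p = 0.043, and adjusted p = 0.708 with an estimated correlation). It did not pass without 6 h replicate 1 (0.0651) or 18 h replicate 1 (0.349), with offset 50 (0.0506) or with the strict detection filter (0.0791). Naive pluripotency had 4 of 17 lower, 5 when adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.708 with an estimated correlation), and did not pass without 6 h replicate 3 (0.0943) or 18 h replicate 1 (0.116). Trophectoderm and placenta had 4 of 14 higher, also 4 when adjusted over the list alone (adjusted p = 0.043, and adjusted p = 0.708 with an estimated correlation), Cdx2 rising by 2.11 (SE 0.30, adjusted p = 0.00143). That list did not pass without 0 h replicate 2 (0.056), 6 h replicates 1 (0.0579) or 3 (0.115), 18 h replicates 1 (0.0928) or 2 (0.101), with offset 50 (0.0506), with the strict filter (0.0846) or with the mean of probes (0.0511). With the block, HDAC complex partners (0.0445) and cholesterol synthesis (0.0449) passed as well. HDAC complex partners also passed without 2 h replicates 1 (0.0498), 2 (0.0485) or 3 (0.0446), 6 h replicates 1 (0.0277) or 2 (0.0292) or 18 h replicate 3 (0.0203). Cholesterol synthesis passed without 2 h replicates 1 (0.0498), 2 (0.0485) or 3 (0.0319), 6 h replicate 2 (0.0224) or 18 h replicate 1 (0.047). Both passed under several other settings (0.0141 to 0.0487 and 0.0358 to 0.0487). Apoptosis regulators passed with 75th percentile scaling (0.0474), no background correction (0.0487), the authors' values (0.0485) or no filter (0.0396). Heat shock and unfolded protein response passed with 75th percentile scaling (0.0324), no filter (0.0393) or without 18 h replicate 1 (0.0201). Without 18 h replicate 3, endoderm (0.0263), the 2-cell-like state (0.0324) and mitosis (0.0159) passed. With fry, core pluripotency (0.224), naive pluripotency (0.257) and trophectoderm and placenta (0.0973) did not pass.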

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

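Of the tests in this part, the groupings within replicate numbers were chosen only after the result of the free groupings was seen. The results below are those where the change itself differed between 2 exposure times, tested directly between the times, and those in probes that the comparisons of genes did not use. Between 2 h and 6 h 1502 genes differed, among them 60 of the 126 genes named by rule. The pluripotency factors Nanog (-1.71), Klf4 (-1.34), Esrrb (-1.33) and Zfp42 (-1.83) had lower log2 signal at 6 h than at 2 h. So did, as lists, core pluripotency (median -0.66), naive pluripotency (-0.97), mitosis (-0.32), HDAC complex partners (-0.38), histone acetyltransferases and BET readers (-0.35), Polycomb subunits (-0.28) and ribosome biogenesis with MYC targets (-0.33). Histone genes with polyadenylated transcripts (0.26, or 0.17 with undetected members at their bound), cholesterol synthesis (0.52) and immediate early genes (0.54) had higher medians at 6 h. None of these 10 lists passed with an estimated correlation (adjusted p 0.564 to 0.71), and mitosis, ribosome biogenesis, immediate early genes (each 0.136) and cholesterol synthesis (0.199) did not pass with fry.

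Between 6 h and 18 h 1287 genes differed, among them 39 of the genes named by rule. Pou5f1 was the only 1 of the 9 fixed genes tested to differ there, at -1.78. The germline list was higher at 18 h than at 6 h (median 0.85), as was trophectoderm and placenta (0.30), while core pluripotency (-0.62), naive pluripotency (-0.21) and DNA replication (-0.21) were lower. Without 18 h replicate 1 the core pluripotency median was -0.30 and the naive pluripotency median -0.25, and neither list passed. None of these 5 lists passed with an estimated correlation (adjusted p 0.0607 to 0.708), and core pluripotency, naive pluripotency and trophectoderm did not pass with fry (0.0973 to 0.257).

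Of 3000 kept probes without a named gene, 58 changed at 2 h (30 higher, 28 lower), 594 at 6 h (271 higher, 323 lower) and 758 at 18 h (354 higher, 404 lower) against the 0 h arrays. They were tested in the same way and left out of the gene counts.

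Other splits of the same arrays were tested for each count of genes. For each comparison of 3 arrays with 3, the real split was the only 1 of the 10 possible splits with as many genes by limma, which are too few splits for a share under 0.05. The real counts were 395, 3591, 4200, 1502 and 1287 genes at 2 h, 6 h, 18 h, 6 h against 2 h and 18 h against 6 h, and the highest of the other splits gave 0 each time. Every other split mixes the 2 groups, so any real difference between them enters the spread and lowers the count. The counts of 0 therefore add little. At an unadjusted p under 0.05 the other splits gave at most 982, 1211, 1907, 672 and 774 genes, where the real ones gave 2057, 4785, 5275, 3213 and 3089. Among the 4 of 10 splits that, like the real one, part all 3 same-numbered pairs, the highest of the others was also 0. For the test over the 4 times, the real grouping was the only 1 of 100 groupings of the 12 arrays to give 5045 genes or more, the highest of the others giving 2220. Since same-numbered arrays deviate together, 100 groupings that permute the times within each replicate number were drawn as well. The real one was again the only 1 to give as many, the highest of the others giving 2552, and with the replicate number as a block in the model 6085 genes against 4273. In each of these 3 draws the share was 1 of 100, the lowest that 100 groupings can give. Regrouping these arrays cannot exclude chance differences between cultures, since the arrays of a group may not be separate cultures.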

How the results depend on the processing

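All alternatives below were fixed before the data were examined. Direction was compared only where a named gene or list passed in the main fit, the alternative or both, and there none reversed. Of 15115 values for the named genes 14258 kept their side of the threshold, 593 fell short of it and 264 newly passed. Of 4030 values for lists 3835 were kept, 75 fell short and 120 newly passed. The number of lists passing at 18 h, 12 at the preset correlation, was 0 with an estimated correlation, 17 with fry, and 12 (without 0 h replicate 1) to 14 (without 0 h replicate 3) with an array left out. The count at 2 h (395) was 262 with scaling to the 75th percentile, where 65 rather than 122 genes were lower, 677 with array weights, and 217 (173 higher, 44 lower) with only the groups compared. With array weights the count between 2 h and 6 h was 2859 rather than 1502 and the count of genes changed alike at all 3 times 419 rather than 260. The cause was not tested for these.

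With the replicate number as a block the counts were 763, 4386, 4959, 2248 and 2112 (2 h, 6 h, 18 h, 6 h against 2 h, 18 h against 6 h), and 395 of 395, 3590 of 3591, 4198 of 4200, 1502 of 1502 and 1287 of 1287 genes stayed called. For all 3 times the block gave 470 rather than 260. Among named genes and lists the block moved Sox2 at 2 h, Esrrb between 6 h and 18 h and 7 list calls, given in the report, and 48 calls of other named genes, all newly passing, and no other. A block by slide was not run, because the files name no slide.

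Leaving out 1 array gave 135 (0 h replicate 3) to 571 (18 h replicate 1) genes at 2 h, 2577 (6 h replicate 1) to 3850 (18 h replicate 1) at 6 h, 3152 (18 h replicate 1) to 4394 (0 h replicate 2) at 18 h. It gave 540 (6 h replicate 1) to 1826 (0 h replicate 2) between 2 h and 6 h, 556 (6 h replicate 3) to 1573 (0 h replicate 2) between 6 h and 18 h, 4272 (6 h replicate 1) to 5132 (0 h replicate 2) over the 4 times, and 89 (0 h replicate 3) to 294 (18 h replicate 1) alike at all 3 times. Fewer arrays leave the test less power, and which genes changed was not followed. Counts of 2-fold changes depended on the background: 174, 1284, 1642, 498 and 411 genes (2 h, 6 h, 18 h, 6 h against 2 h, 18 h against 6 h) became 42, 447, 601, 113 and 105 without background correction, 42, 453, 613, 118 and 108 with the authors' values, and 92, 750, 982, 237 and 223 with an offset of 50, since background left in the signal pulls ratios towards 1. At 2 h the 2-fold count was 102 without 0 h replicate 3 and 108 without 2 h replicate 1. Signal over background limits dim genes: a gene that no array of a group detected has only a lower bound on its change.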

Other observations

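Of the tests in this part, those of overall array signal, of a poor array, of a mislabelled array and of the detection filter, the value over genes brighter than the median for same-numbered arrays, and the choice of gene families by symbol were made only after the results were seen. Gene families were looked for among the 126 symbol stems shared by at least 10 tested genes, with Fisher's exact test against all other genes tested, adjusted over both directions within each time. They were not kept apart from the fixed lists, which hold 8 of the 10 Cdkn genes, 4 Hspa, 4 Slc and 2 Kdm genes, Pramel16 and Zfp42. The exact test counts genes as independent, so correlation between the genes of a stem can make the p-values below, at every time, too small. At 18 h the Pramel genes, whose products are expressed mainly in germ cells and early embryos, had 8 of 11 higher and 0 lower with a median log2 change of 1.21 (adjusted p = 0.0278), with 8 higher under each other scaling too. It was 7 with array weights and without 0 h replicate 2 or 18 h replicate 1. Pramel37 rose by 1.78 (SE 0.31, adjusted p = 0.000645), Pramel20 by 1.48, Pramel17 by 1.46 and Pramel16 by 1.44, although probes of such close relatives can cross-hybridize. Of 231 tested genes with the stem Zfp, most of them zinc finger proteins, 56 fell and 20 rose at 18 h (adjusted p = 0.0409 for more falls and 6.42e-05 for fewer rises), with 38 to 52 lower under the other scalings and 36 without 18 h replicate 1. Of 33 genes of large ribosomal subunit proteins (Rpl) 4 fell and 0 rose at 18 h (adjusted p = 0.0409 for fewer rises by the exact test). None rose under any alternative, and 22 fell with scaling to the 75th percentile. The Cdkn stem had 7 of 10 higher and 1 lower (adjusted p = 0.0488).

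At 6 h histone demethylase genes with the stem Kdm had 8 of 14 lower and 1 higher (adjusted p = 0.0408 by Fisher's exact test), 7 to 9 lower under the other scalings and 6 without 0 h replicate 3. The stem did not pass at 18 h (6 lower, 2 higher, adjusted p = 0.26). Of its single members at 18 h, chosen after their values were seen, Kdm6a, a demethylase of the mark that Polycomb sets, stood at -1.71 (SE 0.26, adjusted p = 0.000258) and Kdm4c at -1.56, while Kdm6b, its relative, stood at 0.71 and Kdm1b at 1.00. Solute carriers (Slc) had 59 of 214 higher and 29 lower at 6 h (adjusted p = 0.0487), and did not pass at 18 h (57 higher, 34 lower, adjusted p = 0.482). Of 64 olfactory receptor genes (Olfr) 0 rose and 3 fell at 18 h (adjusted p = 6.42e-05 for fewer rises by the exact test on limma calls), and at most 1 rose under any alternative. Their median log2 change was 0.01, and whether their probes lay near the array floor was not tested. At 2 h chaperone genes of the Hspa stem had 4 of 10 higher (adjusted p = 0.015), but 0 without 0 h replicate 3, 2 h replicate 1 or 2 h replicate 2, and 2 without 0 h replicate 1, 2 h replicate 3 or 6 h replicate 1. Between 0 h and 18 h, 298 genes went from detection on no array to detection on all 3 and 80 the other way, against 199 and 77 at 6 h and 40 and 38 at 2 h.

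Arrays with the same replicate number deviated from their group means together, and 35 of 36 comparisons found an array closest to its own number. Dim probes near the floor do not account for this, since the mean correlation was 0.327 over 8211 genes detected on all 12 arrays and 0.363 over genes brighter than the median, against 0.274 over all genes. Overall array signal does not either, since 7 of 18 same-numbered pairs deviated to opposite sides in mean signal and still had a median correlation of 0.210. A shared culture or processing day may link them and stays open, because the labels name none.

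Among genes that changed at 18 h, those dim at 0 h mostly rose and bright ones mostly fell: in 5 equal groups of genes from the dimmest to the brightest, 96.7%, 64.7%, 50.5%, 45.9% and 40.7% were higher, and the rank correlation of 0 h level and change over all genes tested was -0.229. Noise in the 0 h baseline is argued against by a median correlation of -0.212 when level and change came from different control arrays, and quantile normalization by -0.256 with scaling to the 75th percentile. The detection filter kept a gene undetected at 0 h only where later arrays detected it: without the filter 7.43% of genes as dim as the dimmest group changed rather than 28.9% and the correlation was -0.111, and although 94.6% of those changed were higher, genes at the floor can hardly be called lower with or without it, so the share of the filter in this pattern stays open. An array floor that hides falls of dim genes remains a candidate explanation, since the correlation was -0.0406 among genes brighter than the median, although a narrower range of levels lowers a correlation in itself. The exposure may also raise silent genes in particular, which was not tested apart from the floor.

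The 18 h replicate 1 array stood apart from the other 18 h arrays, at 57.3 on the first principal component beside 33.2 and 30.8, and its distance to the mean of those 2 was 1.1 times their distance to each other (0.751 and 0.791 for replicates 2 and 3 in its place). A poor array is argued against by its 18031 detected probes, within the 16813 to 18111 of the others, and a mean signal within their range, and a mislabelled one by its correlation of 0.968 with the closest array of another time, below 0.977 with an 18 h array. For quantile normalization no value decides: the ratio was 0.903 with 75th percentile scaling, but the bound set beforehand already lay above the value it was to test, and replicate 3 then had the higher ratio (0.958). Its deviation from the other 18 h arrays correlated across genes at 0.545 with the change at 6 h, so a culture further along the same response is a candidate explanation, as a hypothesis found and tested on the same data. Pou5f1 and the other pluripotency factors fell at 18 h with and without this array, Sox2 excepted, which missed the threshold without it.

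A further hypothesis, that long genes fell, was tested because slowed elongation would lower long genes most. The rank correlation of gene length and 18 h change across 11429 genes (99.9% of those tested) was -0.0425, beside -0.0370 at 2 h and -0.0474 at 6 h. Of 5 equal groups by length, the longest had 430 higher and 403 lower and the shortest 527 higher and 343 lower, a lean towards the hypothesis. From the shortest group to the longest, 343, 338, 365, 350 and 403 genes fell. The median log2 change was -0.00996 in the longest group and 0.0474 to 0.0651 in the others. Falls at 18 h were thus not confined to long genes, but these values cannot exclude a partial effect of length. Elongation itself was not measured.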
